A study of Mus musculus with 8 samples.

How the data were processed

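RNA was sequenced from CD31-positive, tdT-positive cells sorted from mouse bone marrow, in 4 KRasG12D and 4 WT libraries. Mice had received tamoxifen on 4 consecutive days per the labels' protocols. The authors deposited 1 table of FPKM values, fragments per kilobase of transcript and per 1000000 mapped fragments, with 1 column per library and 1 row per gene symbol. Bowtie2, Cufflinks, Cuffdiff and build mm10 are named in the submitters' processing notes, and their versions, settings and annotation are not given in the sources used here. FPKM removes depth and length only on average: a library dominated by a few abundant genes lowers the others, very short RNAs get unstable values, and Cufflinks can return 0 where estimation fails. How shared reads were split between near-identical genes is not given in the sources used here either. Columns were matched to samples through the animal or sample number in the labels, and groups and replicate numbers were taken from the sample titles. The table held 0 columns of other samples.

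Depth was estimated, since the table holds no counts. For 5377 genes with a single transcript longer than 2000 bases, the FPKM value times transcript length (less an assumed fragment length of 150 bases) was searched for the number of fragments at which values of up to 6 fragments came out whole. At the best number 88.1% to 94.2% of these values lay within 0.1 of a whole number, where chance gives 20%. The method was tested on simulated data of known depth. The estimates ranged from 36.9 to 53.9 in units of 1000000 fragments. FPKM totals ranged from 555121 to 730476. Whole counts were not recovered for genes with several transcripts, so no count test was run.

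Values were analysed as log2(FPKM + 1) as deposited, for 13375 genes with a mean of at least 1 FPKM over the 8 libraries. A fold change is on this log2 scale with a pseudocount of 1, which understates the change of low genes. The comparison of KRasG12D with WT used limma 3.58.1 in R 4.3.3, with a mean-variance trend, genotype as the only term and Benjamini-Hochberg adjustment at 0.05. The 35 gene lists (pathways, endothelial types and other cell types the sort could hold) were tested with camera at a preset inter-gene correlation of 0.01, with at least 5 tested members, and adjusted over the lists. They were repeated with an estimated correlation and with fry, which asks only whether a list's genes move on balance one way. Each list's mean log2 value per library, and Kras alone, were compared by a two-sided exact permutation test over the 70 splits of 4 against 4. Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined.

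The rule named Kras, then up to 8 genes per direction past the threshold with no overlap between the groups. As none passed, it named the 5 with the smallest p in each direction, as values. For each list described it named up to 2 members with the smallest p, and for lists of other cell types also the most abundant member. Levels of further blood and endothelial genes (S100a8, Mpo, Elane, Igha, Ptprc, Cdh5, Tek, Kdr, Pecam1, Erg, Vwf, Stab2), Junb, Xist and Ddx3y were chosen after the values were seen. Coordinates, gene types and exon lengths came from GENCODE M21, which uses GRCm38, the assembly that mm10 also names; 95.5% of the symbols matched it, and 97.5% of the tested genes had a length.

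The gene test was tested on simulated data with the means and spread of the 13375 genes. With 100 genes changed 2-fold and 100 changed 4-fold in each of 20 runs, all with a mean log2 value above 2, it recovered 67.8% and 95.0% of them, with a mean of 9.05 false calls per run. Genes were drawn independently, each with the same spread in every library. Differences between libraries that many genes share were left out, so these rates are not the power of the real comparison. A shift of 0.5 on the log2 scale in the ERK pathway list, with independent genes, was called in 20 of 20 runs. The real members of that list had an estimated correlation of 0.39, so these runs do not give the power for correlated genes. Alternatives were pseudocounts of 0.1 and 5, no filter or a minimum mean of 5 FPKM, 3 other scalings of the libraries (median-of-ratios, upper quartile, quantile), limma without the trend but robust, library weights, the replicate number as a block, a threshold of 0.1, and each library left out in turn. Protein-coding genes only, an Xist covariate and removal of a length trend were added after seeing the data, as was the count at unadjusted p under 0.05. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.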

Results

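The series measured RNA from bone marrow cells of adult mice that a flow cytometer had sorted as positive for CD31 and tdT. CD31 is the protein of Pecam1, an adhesion molecule of endothelial cells that platelets and many white blood cells also carry. Mice had received tamoxifen, the drug commonly used to switch on inducible Cre recombinase, on 4 consecutive days. The labels give 4 libraries as KRasG12D, an activating mutant of the small GTPase Kras, and 4 as WT. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples, which may be partly technical. Xist and Ddx3y, given below, place female and male cells in each genotype. Its libraries therefore did not all come from the same mouse. The deposited table held FPKM for 49277 gene symbols, of which 22656 were listed at 0 in every library. Between 19659 and 23046 symbols per library had a value above 0. The stepped low values gave an estimated depth, in units of 1000000 fragments, of 47.7, 49.2, 53.9 and 36.9 for KRasG12D 1 to 4. For WT 1 to 4 it was 40.3, 36.9, 47.5 and 49.8. At these depths 1 FPKM on a transcript of 1 kb stood for 36.9 to 53.9 fragments.

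Kras itself was read first, in every library. It lies on the minus strand of chromosome 6, from 145216699 to 145250239 in build mm10. The libraries KRasG12D 1 to 4 had 33.8, 36.9, 36.6 and 20.5 FPKM, and WT 1 to 4 had 23.5, 24.6, 19.5 and 19.8 FPKM. The group levels were 31.9 ± 7.75 and 21.9 ± 2.56 FPKM (SD, n = 4 each), a difference of 0.50 on the log2(FPKM + 1) scale. A two-sided exact permutation test gave p = 0.0857, where 0.0286 is the smallest p that 4 against 4 allows, and limma with Benjamini-Hochberg adjustment gave an adjusted p of 1.00. The library labelled KRasG12D 4 lay inside the WT range. Without it the difference was 0.69 with an exact p of 0.0286, the smallest possible, and the limma adjusted p was 0.31. It was the only KRasG12D library inside the WT range, so leaving it out fixed this exact p, which therefore decides nothing. The genotype changes the coding sequence of Kras, which FPKM values cannot show, so the level does not by itself check the labels.

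**Figure D1:**
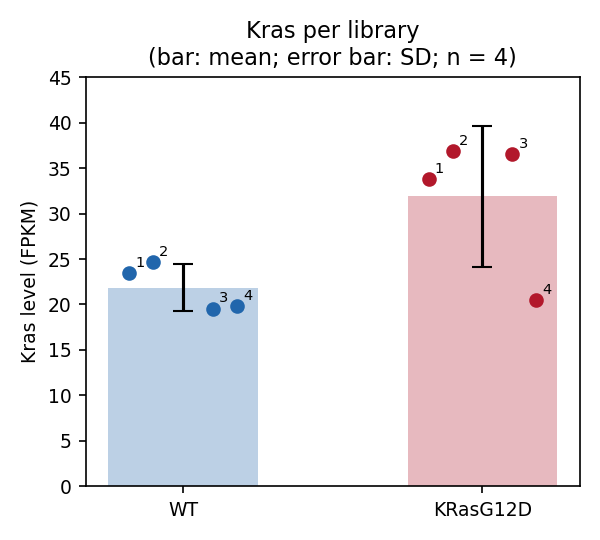
Kras level in FPKM in each library (points, numbered by replicate) with the group mean (bar) and SD (error bar), n = 4 per genotype. KRasG12D 1 to 3 lie between 33.8 and 36.9 FPKM, and KRasG12D 4 lies at 20.5 FPKM among the WT libraries.

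Transcripts of blood cells made up far more of the sorted population's RNA than endothelial transcripts did, in both genotypes. S100a9, a calcium-binding protein of neutrophils, had a mean level of 19330 ± 4135 FPKM (SD, n = 8), and its partner S100a8 had 12972 ± 2066 FPKM. The neutrophil granule enzymes Mpo and Elane had means of 3546 ± 824 and 2892 ± 735 FPKM, and the lysozyme gene Lyz2 of monocytes and neutrophils had 3439 ± 493 FPKM. Igkc and Igha, constant segments of antibody chains, had 8623 ± 2273 and 3800 ± 1092 FPKM. Ptprc, which encodes the pan-leukocyte protein CD45, had 111 ± 30.5 FPKM. In contrast, the endothelial cadherin Cdh5 had 3.30 ± 1.68 FPKM, the angiopoietin receptor Tek 1.12 ± 0.580 FPKM and the VEGF receptor Kdr 1.83 ± 1.24 FPKM (all SD, n = 8). Other endothelial genes were higher, with Pecam1 at 27.1 ± 5.17 FPKM, the transcription factor Erg at 12.7 ± 2.75 FPKM and Vwf, which platelets also carry, at 9.04 ± 2.43 FPKM. Stab2, a scavenger receptor of marrow sinusoids, had 3.48 ± 2.60 FPKM.

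The 17 genes of the neutrophil list held 8.89% ± 1.19 of the FPKM total in KRasG12D and 8.83% ± 0.644 in WT (SD, n = 4 each), with p = 0.971 by a two-sided exact permutation test. The 22 genes of the pan-endothelial list held 0.0221% ± 0.00398 and 0.0249% ± 0.00683, with an exact p of 0.486. In all 8 libraries the median member of each of 9 blood lineage lists lay above the median member of the pan-endothelial list. The closest of these was the megakaryocyte and platelet list, whose median was at least 1.15 times the pan-endothelial one in every library. The furthest was the neutrophil list, at least 226 times above it.

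**Figure D2:**
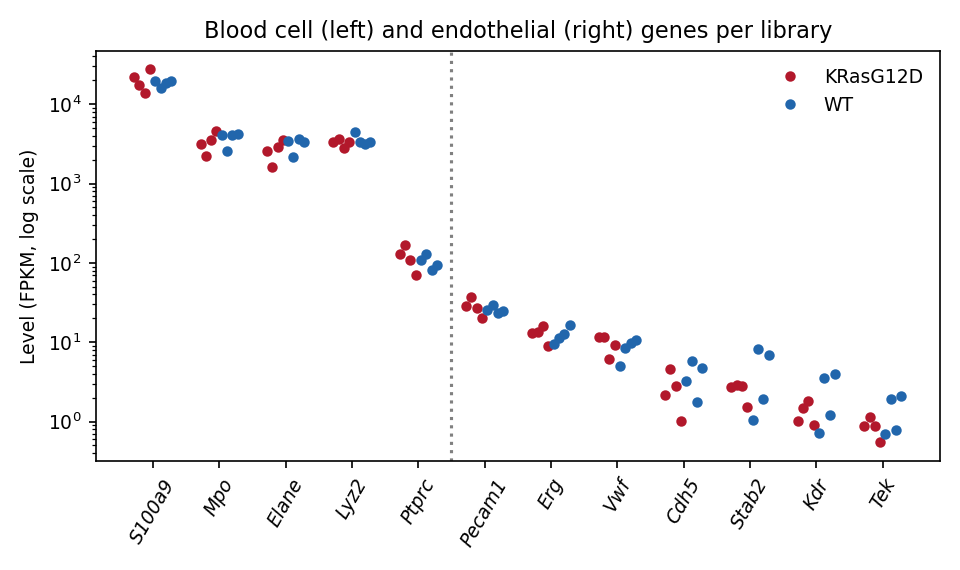
Levels in FPKM on a log axis of 5 blood cell genes (left of the dotted line) and 7 endothelial genes (right), with 1 point per library, KRasG12D in red and WT in blue. Ptprc lies between 70.6 and 166 FPKM and Cdh5 between 1.03 and 5.87 FPKM over the 8 libraries.

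The design text asks which genes differ in level between WT and KRasG12D endothelial cells. None of 13375 genes tested passed the adjusted threshold. Because blood cell transcripts far exceeded endothelial ones, the gene and list tests read the sorted population as a whole. A change confined to endothelial cells may go unseen in them. Of the 10 named here, the 5 with the smallest p in each direction, 3 were antibody segments and 3 were very short genes. The kappa chain segments Igkv1-135 and Igkv4-53 had 344 ± 34.0 and 170 ± 34.6 FPKM in KRasG12D against 135 ± 32.4 and 11.5 ± 12.1 FPKM in WT (SD, n = 4 each). Their log2 differences were 1.38 (SE 0.18, limma adjusted p = 0.195) and 4.30 (SE 0.62, limma adjusted p = 0.243). The heavy chain segment Ighv10-3 had 13.7 ± 12.1 and 40.3 ± 11.8 FPKM, a log2 difference of -1.73 (SE 0.45, limma adjusted p = 1.00). Variable segments belong to families of similar sequence and may share reads with their relatives, which was not tested, so their levels are uncertain. Izumo1r, the folate receptor 4 of regulatory T cells, had 4.63 ± 1.42 FPKM in KRasG12D and 1.24 ± 0.547 FPKM in WT, a log2 difference of 1.33 (SE 0.24, limma adjusted p = 0.875). The protein-coding genes with the smallest p in the other direction were the zinc finger gene Zfp429, with 1.75 ± 0.408 and 3.71 ± 0.726 FPKM, and the tetraspanin Tspan17, with 5.93 ± 1.28 and 10.1 ± 1.46 FPKM. Their log2 differences were -0.77 and -0.68 (limma adjusted p = 1.00 for both). The processed pseudogene Gm6195 had 16.6 ± 1.36 and 24.2 ± 3.81 FPKM and may share reads with its parent gene.

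The 3 remaining genes, all short, are given by library, because an exact 0 in this table can be a failed estimate: Junb, an early response gene that blood cells use, was itself listed at 0 in 6 of the 8 libraries. The small nuclear RNA Gm25541 was listed at 0 in all 4 WT libraries and had 6.42, 23.8, 8.39 and 34.0 FPKM in KRasG12D 1 to 4 (limma adjusted p = 0.164). The pseudogene Gm15067 was also listed at 0 in all 4 WT libraries, with 3.29, 2.59, 1.18 and 3.20 FPKM in KRasG12D 1 to 4 (limma adjusted p = 0.195). The small nucleolar RNA Snora31 had 26.6, 15.7, 3.41 and 42.2 FPKM in WT 1 to 4, and 3.38 FPKM in KRasG12D 3, and was listed at 0 in the other KRasG12D libraries (limma adjusted p = 1.00). Their exons total 126, 156 and 130 bases.

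Across all genes, limma with Benjamini-Hochberg adjustment called 0 higher and 0 lower in KRasG12D. The lowest adjusted p was 0.164. At an unadjusted p under 0.05 there were 285 genes, 146 higher and 139 lower, where chance alone gives 669. The groups did not overlap in 210 genes, 1.57% of those tested, and chance gives 2.86%. The median half-width of the 95% interval was 0.39 on the log2(FPKM + 1) scale, and 95.1% of genes had a half-width under 1. For these, a true difference 1 away from the estimate on that scale lay outside the interval. In low genes, 1 on that scale is more than a 2-fold change in FPKM. Without the library labelled KRasG12D 4 the adjusted count was still 0, and the count at unadjusted p under 0.05 was 1584. Leaving out KRasG12D 1, KRasG12D 3 or WT 3 called 2, 1 and 3 genes, all of them small RNAs, a pseudogene or antibody segments.

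Genes that RAS signalling is best known to induce had both positive and negative differences, and none passed the test. Of 24 ERK pathway feedback and target genes, 16 were tested and 0 passed, also when adjusted over the list alone, and 7 had a positive difference. Dusp5, a phosphatase induced by ERK, had 19.0 ± 1.76 FPKM in KRasG12D and 14.7 ± 1.72 FPKM in WT, a log2 difference of 0.35 (SE 0.12, limma adjusted p = 1.00). Emp1, an epithelial membrane protein, had 17.2 ± 2.29 and 22.9 ± 8.46 FPKM. The list's mean log2 difference was 0.00, and camera gave an adjusted p of 0.87 (0.97 with an estimated correlation). The mean was negative without KRasG12D 1, KRasG12D 2, WT 3 or WT 4, with -0.09 without KRasG12D 2 the lowest. It was highest, at 0.13, without KRasG12D 4, where camera with the preset correlation gave an adjusted p of 0.21. Its mean level per library was 2.38 ± 0.23 in KRasG12D and 2.37 ± 0.11 in WT on the log2(FPKM + 1) scale (SD, n = 4), with a two-sided exact p of 1. Among immediate early genes, the nuclear receptor Nr4a1 had 44.9 ± 12.6 and 27.7 ± 5.71 FPKM, and 0 of 19 tested members passed over all genes or adjusted over the list alone. The list of RAS-MAPK components, Kras included, had 0 of 24 by either adjustment and a mean log2 difference of 0.03, which with a library left out ranged from -0.02 without KRasG12D 2 to 0.08 without KRasG12D 4.

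In the lists of vessel growth, matrix and flow-responsive genes 0 members passed, over all genes or adjusted over the list alone. Vegfa, the main vascular growth factor, had 13.0 ± 1.21 FPKM in KRasG12D and 15.7 ± 1.32 FPKM in WT, a log2 difference of -0.25. The matrix genes Fn1 and Tgfbi had 143 ± 23.9 and 94.4 ± 16.0 FPKM in KRasG12D against 185 ± 32.6 and 122 ± 16.4 FPKM in WT, with log2 differences of -0.37 for each. The flow-responsive adaptor Slc9a3r2 had 6.60 ± 1.15 and 4.05 ± 1.09 FPKM, and the anticoagulant Tfpi had 17.2 ± 4.34 and 27.0 ± 7.95 FPKM, with log2 differences of 0.60 and -0.60. The limma adjusted p was 1.00 for all 5. In the NF-kB and endothelial activation list, Tnfaip3, a brake on that pathway, had 23.1 ± 6.38 and 17.4 ± 0.594 FPKM, with camera adjusted p = 0.107 for the list (0.93 with an estimated correlation).

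Interferon-stimulated genes were slightly higher as a group in KRasG12D by the gene list test with a preset correlation, but not when the correlation was estimated. Of 22 tested members 20 had a positive difference, with a mean of 0.23 on the log2 scale and 0 passing over all genes or adjusted over the list alone. Gbp2, a guanylate-binding protein, had 6.73 ± 0.532 FPKM in KRasG12D and 5.12 ± 0.504 FPKM in WT, and the chemokine Cxcl10 had 3.27 ± 1.40 and 1.70 ± 1.01 FPKM. Camera gave the list an adjusted p of 4.79e-05 with the preset correlation of 0.01 and an adjusted p of 0.93 with an estimated correlation. Without KRasG12D 2 the mean difference was 0.08 and the preset-correlation adjusted p was 0.111, and without WT 4 they were 0.15 and 0.0105. The plasmacytoid dendritic cell list below was also highest in KRasG12D 2 (5.94, where this list had 3.86) and lowest in WT 4 (4.91 and 2.93), so the tests did not separate the interferon difference from that list. Within genotypes the 2 list means correlated at a Pearson r of 0.81 over the 8 libraries, and at 0.41 without KRasG12D 2. The mean level per library was 3.41 ± 0.30 against 3.17 ± 0.22, with an exact two-sided p of 0.229.

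Cell cycle and p53 genes had small differences of opposite sign. Of 34 tested cell cycle genes 4 had a positive difference, and the mean was -0.10 on the log2 scale. The ubiquitin-conjugating enzyme Ube2c had 159 ± 14.5 FPKM in KRasG12D and 182 ± 21.5 FPKM in WT, and the spindle checkpoint kinase Bub1 had 21.2 ± 2.42 and 23.7 ± 1.93 FPKM. Of 16 p53 target and senescence genes 14 had a positive difference, with a mean of 0.15. The pro-apoptotic gene Pmaip1 had 12.1 ± 2.80 and 8.52 ± 1.74 FPKM, and the death receptor Fas had 7.63 ± 1.36 and 6.22 ± 0.941 FPKM. In both lists 0 members passed over all genes or adjusted over the list alone. Camera adjusted p-values were 0.000953 for the cell cycle and 0.00569 for p53 targets with the preset correlation, and adjusted p = 0.93 and 0.89 with an estimated correlation. The cell cycle call was lost without KRasG12D 2, KRasG12D 4, WT 1 or WT 3, with means of -0.07, -0.09, -0.07 and -0.07, and without WT 2 the mean was -0.17. The p53 call was lost without KRasG12D 2, KRasG12D 4 or WT 1, with means of 0.09, 0.15 and 0.12, so without KRasG12D 4 neither mean was much smaller.

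Markers of several blood lineages had positive mean differences in KRasG12D. The plasma cell list had 10 of 10 tested members above 0 and a mean log2 difference of 0.25, with Igkc at 10188 ± 1430 FPKM in KRasG12D and 7058 ± 1866 FPKM in WT, and the heavy chain gene Ighm at 1359 ± 484 and 934 ± 112 FPKM. The plasmacytoid dendritic cell list had 8 of 9 above 0 and a mean of 0.28, with the protease Klk1 at 40.0 ± 20.9 and 22.7 ± 7.66 FPKM, Cox6a2 at 37.5 ± 8.85 and 29.9 ± 3.77 FPKM, and the most abundant member Bst2 at 232 ± 64.0 and 207 ± 31.6 FPKM. The erythroid list had 14 of 15 above 0 and a mean of 0.24, with the anion exchanger Slc4a1 at 15.9 ± 8.13 and 9.32 ± 2.53 FPKM, the heme enzyme Alas2 at 14.1 ± 2.02 and 10.7 ± 5.42 FPKM, and beta-globin Hbb-bs at 345 ± 79.8 and 263 ± 86.3 FPKM. The T and NK cell list had 12 of 17 above 0 and a mean of 0.13, with the coreceptor Cd4 at 14.5 ± 4.45 and 9.28 ± 1.92 FPKM, the receptor segment Trbc1 at 25.6 ± 3.97 and 21.9 ± 1.34 FPKM, and Nkg7 at 276 ± 47.2 and 277 ± 48.8 FPKM.

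In these 4 lists 0 members passed over all genes or adjusted over the list alone. Camera adjusted p-values with the preset correlation were 0.000452 for plasma cells, 0.000953 for plasmacytoid dendritic cells, 0.000693 for erythroid cells and 0.00897 for T and NK cells. With an estimated correlation they were adjusted p = 0.89, 0.93, 0.93 and 0.93. The neutrophil and the monocyte and macrophage lists were not called, with mean differences of 0.02 and 0.10. With a library left out the first was -0.08, -0.01 and -0.01 without KRasG12D 1, KRasG12D 4 and WT 2 and at most 0.12 (without KRasG12D 3), and the second ranged from 0.02 without WT 3 to 0.24 without WT 2. Within the last, the macrophage complement receptor Vsig4 had 3.33 ± 1.06 and 1.46 ± 1.03 FPKM and the monocyte chemokine receptor Ccr2 had 81.2 ± 8.41 and 110 ± 25.3 FPKM. Immunoglobulin genes held 4.68% ± 0.639 of the FPKM total in KRasG12D and 3.41% ± 0.709 in WT, with an exact two-sided p of 0.0571. Small RNA genes held 1.84% ± 1.31 and 0.660% ± 0.180, with the same exact p of 0.0571 and the highest share, 3.72%, in KRasG12D 2. The dendritic call was lost without KRasG12D 2 (mean 0.11), the erythroid call without KRasG12D 4 (0.29) or WT 1 (0.10), and the T and NK call without KRasG12D 2 (0.01), KRasG12D 4 (0.17), WT 3 (0.04) or WT 4 (0.10). The erythroid mean was 0.15 without KRasG12D 1 and 0.39 without WT 3, and the T and NK mean 0.21 without KRasG12D 3 and 0.22 without WT 2, with the calls kept.

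Endothelial marker lists did not share a direction. The pan-endothelial, sinusoidal and lymphatic lists had mean log2 differences of -0.24, -0.22 and -0.29, the venous list -0.02 and the arterial list 0.10, with 5 of 7 tested members above 0. These depended on the libraries included: the sinusoidal mean was -0.00395 without WT 2, -0.05 without WT 4, -0.35 without WT 3 and -0.46 without WT 1. The lymphatic mean was -0.11 without KRasG12D 4 and -0.15 without WT 2. Leaving out single libraries does not show that WT 2 and WT 4 were high together. Their sinusoidal list levels were 3.573 and 3.421 (log2), where WT 1 and WT 3 had 2.265 and 2.601 and KRasG12D libraries had 2.608 to 2.815. The venous mean was positive without KRasG12D 3, KRasG12D 4, WT 2 or WT 4 (0.03, 0.05, 0.11 and 0.05), and the arterial mean was -0.15 without KRasG12D 2, 0.20 without KRasG12D 1, 0.24 without KRasG12D 4, 0.21 without WT 1 and 0.02 without WT 4. Of 17 tested pan-endothelial genes 5 had a positive difference. The calcitonin receptor partner Ramp2 had 1.39 ± 0.503 FPKM in KRasG12D and 2.55 ± 1.27 FPKM in WT, and the tight junction gene Cldn5 had 3.03 ± 1.06 and 6.77 ± 4.59 FPKM. Plvap, the diaphragm protein of fenestrated vessels, had 6.55 ± 0.682 and 14.6 ± 9.79 FPKM. In the pericyte and smooth muscle list Kcnj8, a potassium channel, had 0.914 ± 0.115 and 2.36 ± 1.16 FPKM. Its values were 3.40 and 3.32 FPKM in WT 2 and WT 4, and 1.27 and 1.46 FPKM in WT 1 and WT 3. In the arterial list Ly6a, which blood progenitors also express, had 38.8 ± 16.4 and 21.7 ± 6.28 FPKM. Its log2 difference of 0.75 weighed heavily on the arterial mean of 0.10 over 7 members. None of these members passed, and 0 passed adjusted over the list alone. Camera gave the pan-endothelial list an adjusted p of 0.0428 with the preset correlation and an adjusted p of 0.93 with an estimated correlation. The call was lost without KRasG12D 1, KRasG12D 2, KRasG12D 4, WT 2 or WT 4 (means of -0.22, -0.26, -0.21, -0.13 and -0.09), without WT 1 and WT 3 in turn the means were -0.43 and -0.33 with the call kept, and at a minimum mean of 5 FPKM the list's mean was 0.05. Its level varied most among WT libraries, with 2.00 ± 0.11 in KRasG12D and 2.23 ± 0.46 in WT (log2, SD, n = 4) and an exact p of 0.371. Libraries WT 2 and WT 4 had 2.538 and 2.684, and WT 1 and WT 3 had 1.717 and 1.979. KRasG12D libraries had 1.896 to 2.116, so the lower KRasG12D mean rested on WT 2 and WT 4.

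Of the 35 lists, camera called 8 with the preset correlation, 6 higher and 2 lower, and 0 with an estimated correlation. The rotation test fry called 0, with a lowest adjusted p of 0.999. The exact tests of list means called 0 lists, also without adjustment. Without the library labelled KRasG12D 4 camera called 3 lists, those of interferon-stimulated genes, plasma cells and plasmacytoid dendritic cells.

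**Figure D3:**
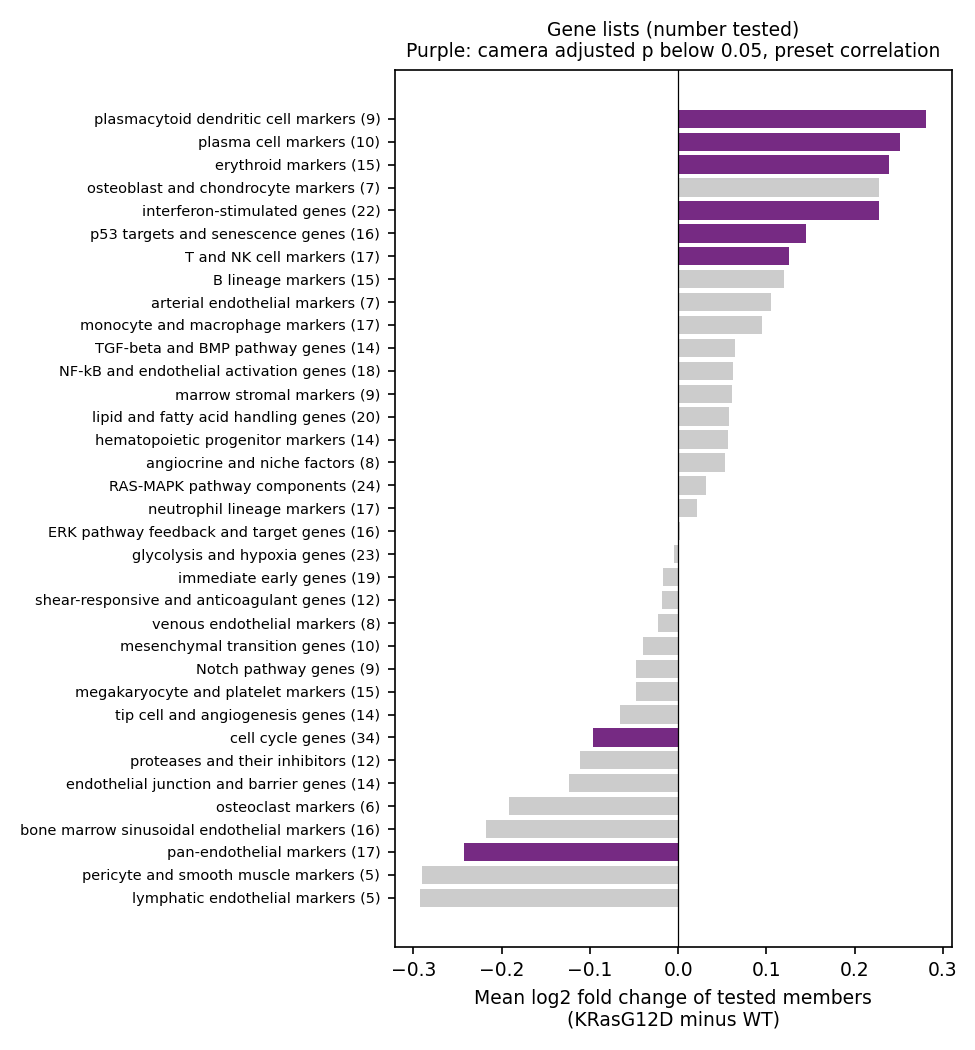
Mean log2 fold change (KRasG12D minus WT) of the tested members of each of the 35 gene lists, with the number tested in brackets. Purple bars are the 8 lists with a camera adjusted p below 0.05 with the preset correlation, of which 0 were called with an estimated correlation.

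The library labelled KRasG12D 4 stood apart from the others. Its root mean square distance from the median library was 0.589 on the log2 scale, where the next, KRasG12D 2, had 0.471. The first principal component took 29.0% of the variance and placed it at 56.6, with the others between -31.4 and 16.1. Ribosomal protein genes held 5.06% of its FPKM total and mitochondrial genes 1.29%, against 3.01% to 4.27% and 1.90% to 2.91% in the others. Across genes, its deviations correlated with exon length at a Spearman rho of -0.41, and those of KRasG12D 1 to 3 at 0.23, 0.26 and 0.18. Those of WT 1 to 4 correlated at -0.01, 0.13, -0.34 and -0.11, and WT 3, the closest, had a distance of 0.410. Genes are not independent replicates, so these values only describe the libraries. Replicates of a genotype correlated at a Spearman rho of 0.917 to 0.961 across genes. Xist, which female cells express, had 132 FPKM in KRasG12D 1 and 187 FPKM in WT 2 and at most 0.248 FPKM elsewhere, so each genotype had 1 such library. Ddx3y, a gene of the Y chromosome, was listed at 0 in those libraries and had 5.68 to 17.2 FPKM in the others. So the libraries of a genotype did not all come from the same mouse.

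**Figure D4:**
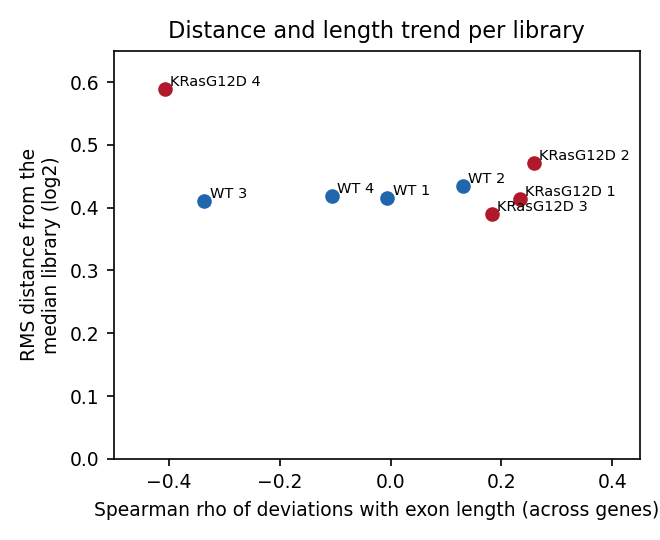
Root mean square distance of each library from the median library (log2 scale, vertical axis) against the Spearman rho of its deviations with exon length across genes (horizontal axis), KRasG12D in red and WT in blue. KRasG12D 4 lies highest, at 0.589, and furthest left, at -0.41.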

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

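The tests of depth and of the genotype label for KRasG12D 4, its comparison with WT 3, the splits with the length trend removed, both tests on blood and endothelial transcripts and the count of splits for changed genes were chosen after the result was seen. Of 190 groups of 4 libraries examined (54 genes, 35 list means and 6 library measures in each genotype), 16 had a library far from the other 3 by Dixon's ratio of the gap to the whole range. Chance gives about 1 in 20, or 9.5.

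KRasG12D 4 was the library apart in 3 of these groups. Its Kras value lay below the other KRasG12D libraries (ratio 0.848; 4.43 against 5.12 to 5.24 on the log2 scale). Its correlation with exon length was -0.41 where the other KRasG12D libraries had 0.18 to 0.26 (ratio 0.887), and its mean of sinusoidal endothelial markers was 2.61 against 2.79 to 2.81 (ratio 0.894). The same depth did not place WT 2 as far: its estimate was also 36.9 in units of 1000000 fragments, and the distance of KRasG12D 4 from the median library was 1.36 times that of WT 2 (interval over genes 1.22 to 1.51). This rests on a single other library, on genes that are not independent and on a bound set after the result was seen. Depth is therefore not excluded. An earlier test at 50 FPKM or more decided nothing, with a ratio to the next largest distance of 1.21 (interval over genes 0.909 to 1.63). A transcript length trend, as degraded RNA may leave, stays open as a part of the cause: WT 3, with a correlation of -0.34, did not stand apart (the distance of KRasG12D 4 was 1.44 times its distance, interval 1.30 to 1.58), while removing the trend took the ratio to the next largest distance from 1.25 to 1.18 (interval over genes 1.05 to 1.28), between the bounds set beforehand for and against it. A wrong genotype label stays open too: its Kras level lay with WT, and its mean Spearman correlation with WT exceeded that with the other KRasG12D libraries by 0.0151. The length trend was not removed for this correlation. WT 1, WT 3 and WT 4 also had negative correlations with exon length (-0.01, -0.34 and -0.11), so the trend alone may bring KRasG12D 4 closer to WT. The other 7 libraries also had a higher mean correlation with WT, by 0.00216 to 0.00951. Their means over KRasG12D libraries include KRasG12D 4 itself, which correlated less well with either group (0.924 with KRasG12D, 0.939 with WT). So their values do not weigh against a wrong label. Incomplete recombination, a biological explanation, was not tested.

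Blood cell transcripts far exceeded endothelial ones in cells sorted for CD31 and tdT. Reads shared between paralogs or pseudogenes are not decided on. The lowest of Ptprc, Mpo and Elane was at least 5.63 times the highest of Cdh5, Tek and Erg in every library. These genes and the bound were chosen after their values were seen, however, and FPKM values do not show which reads were shared. Cells of other types in the sorted population, or their RNA, may be the source, but no test here bears on it: that 9 of 9 blood lineage lists had a median above the pan-endothelial median in all 8 libraries restates the pattern. CD31 is carried by platelets, monocytes, neutrophils and lymphocytes, and the tdT gate would be needed to remove them. How far the gate did so cannot be read from these values, and blood cells that themselves carry tdT remain possible.

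Regrouping the libraries gave counts as large as the real ones. For changed genes this decides nothing, because a real count of 0 is met by all 35 of the 35 splits of the 8 libraries into 4 and 4 (the highest other split called 4). As many genes at unadjusted p under 0.05 as the real 285 came from 24 of 35 splits, with a highest other count of 3175, and as many lists as the real 8 came from 18 of 35, with a highest other count of 17. So chance cannot be excluded for the last 2 counts. The split with 3175 genes, several times the real count, set KRasG12D 1, 2 and 3 and WT 2 against the rest. It was picked as the highest of the 35, and whether it reflects a structure of the samples was not tested. It also parts the libraries with a positive correlation with exon length (0.13 to 0.26) from those with a negative one (-0.01 to -0.41). After removal of the length trend, a check added after seeing this, it gave 2692 genes and the real split 342. Without KRasG12D 4 the real split of 3 against 4 gave 1584 genes, and 4 of 35 splits gave as many, with a highest other count of 2521, so chance cannot be excluded there either.

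The other flagged values follow. Snora31 was at 2.13 (log2) in KRasG12D 3 and listed at 0 in the other KRasG12D libraries (ratio 1). WT 4 was high for Emp1 (5.19 against 4.26 to 4.38, ratio 0.872). WT 1 was high for Fn1 (7.88 against 7.37 to 7.44, ratio 0.863), Tgfbi (7.20 against 6.82 to 6.88, ratio 0.84) and Lyz2 (12.1 against 11.6 to 11.7, ratio 0.838). WT 2 was low for Ube2c (7.23 against 7.59 to 7.60, ratio 0.967), Bub1 (4.45 against 4.67 to 4.71, ratio 0.839) and the cell cycle list (5.65 against 5.91 to 5.94, ratio 0.89), and high for the B lineage list (5.23 against 4.31 to 4.46, ratio 0.841). KRasG12D 3 was high for Bub1 (4.69 against 4.37 to 4.41, ratio 0.88) and Vsig4 (2.56 against 1.90 to 1.98, ratio 0.88). KRasG12D 2 was high for the interferon-stimulated list (3.86 against 3.22 to 3.28, ratio 0.9), and the call of that list was lost without it, and high for Cd300e (4.22 against 3.16 to 3.29, ratio 0.882).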

How the results depend on the processing

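Counts at unadjusted p under 0.05, and fits to protein-coding genes, with an Xist covariate or with a length trend removed, were chosen after seeing the data, as were means of the uncalled lists other than the ERK list with a library left out. Changed genes stayed at 0 in limma except for 1 with a pseudocount of 0.1 (Gm25541) and 0 to 3 with a library left out: 2 without KRasG12D 1 (Gm25541 and Gm25747), 1 without KRasG12D 3 (Gm15067) and 3 without WT 3 (Igkv4-53, Igkv4-90 and Mir5125). The adjusted threshold of 0.1 also gave 0. Genes at unadjusted p under 0.05 numbered 285, against 793 with no filter on low values, where 26621 genes were tested, and 1663 with library weights, and 216 to 1584 with a library left out, the highest without KRasG12D 4. List calls numbered 8, against 0 with an estimated correlation, 0 by fry, and 3 to 11 with a library left out (4 without KRasG12D 2, 3 without KRasG12D 4). The replicate numbers were not taken to pair the samples, since deviations of same-numbered libraries correlated at only 0.03 to 0.17, but all 4 correlations were positive and 4 of 8 libraries correlated best with their own number, so a weak pairing stays open. With the replicate block there were 0 changed genes, 358 at unadjusted p under 0.05 and 11 lists. The Kras difference ranged from 0.42 to 0.69, the highest and the only one past the exact test's threshold being without KRasG12D 4. As this left out the only KRasG12D library inside the WT range, it fixed the exact p and decides nothing. The ERK list, 0.00 in the reported fit, ranged from -0.0888 without KRasG12D 2 to 0.13 without KRasG12D 4 and was negative without KRasG12D 1, KRasG12D 2, WT 3 or WT 4. With library weights it was 0.11. The pan-endothelial list was 0.046 at a mean FPKM of at least 5, where its lowest members are not tested, and its call was also lost with a pseudocount of 0.1, quantile normalization or library weights, though its mean was no smaller (-0.32, -0.24 and -0.24 against -0.24). The T and NK call was also lost with no filter or library weights (0.13 and 0.17 against 0.13), and the p53 call with library weights (0.15 against 0.15). Of 54 genes, Nkg7 was 0.0128, 0.00433 and 0.00179 with median-of-ratios, upper quartile and quantile scaling and 0.0230 with the length trend removed, against -0.00171 in the reported fit, and ranged from -0.14 to 0.12 with a library left out. S100a9 and Bst2 were -0.0495 and -0.0494 with library weights, and ranged from -0.10 to 0.24 and from -0.0174 to 0.26 with a library left out, and Lyz2 from -0.17 to 0.00064. The cause was not tested for any of these. No other of these genes reversed in the settings run. Depth limits genes near 1 FPKM most.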

Other observations

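The tests of both cell types and of the splits for antibody segments below were written down before their results were seen, the last after the spread of the segments was known. Among the 50 genes with the smallest p, 11 were immunoglobulin variable segments, of 182 tested, and 10 of the 11 had a positive difference in KRasG12D. Several others are known from regulatory T cells. Ctla4, an inhibitory receptor, had 4.72 ± 0.842 FPKM in KRasG12D and 2.26 ± 0.390 FPKM in WT (SD, n = 4), and the costimulatory receptor Tnfrsf4 had 5.50 ± 1.16 and 2.55 ± 0.407 FPKM, beside Izumo1r. A further set is known from non-classical monocytes: Treml4 had 27.8 ± 5.97 and 12.04 ± 5.16 FPKM, Cd300e 10.8 ± 4.58 and 3.56 ± 2.09 FPKM, and Cd300ld 14.2 ± 2.91 and 7.34 ± 2.83 FPKM. The limma adjusted p-values of these 5 were 0.938 for Tnfrsf4 and 1.00 for the others, and all were picked after their values were seen.

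A larger share of regulatory T cell RNA in KRasG12D is a hypothesis that these genes raise. Of 12 further regulatory T cell genes, 6 were expressed enough to test (Ikzf2, Tnfrsf18, Icos, Tigit, Cd5 and Il2rb). All 6 had a positive log2 difference, from 0.02 for Il2rb to 0.42 for Cd5. Tnfrsf18, for example, had 11.9 ± 2.36 and 8.81 ± 1.30 FPKM. Their mean log2 value differed by 0.31 (2.57 ± 0.52 against 2.26 ± 0.18), with a two-sided exact p of 0.314. Without KRasG12D 4 the difference was 0.52 with an exact p of 0.0286, the smallest possible. The test does not decide. The general T and NK cell list also had 12 of 17 members above 0, so more T cell RNA of any kind was not separated from this hypothesis.

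More RNA of non-classical monocytes in KRasG12D may be a second hypothesis. Of 12 further genes of that cell type, 11 had a positive difference, among them Ace, with 18.6 ± 9.06 and 8.77 ± 5.35 FPKM, and Adgre4, with 14.6 ± 5.03 and 7.53 ± 3.94 FPKM. The mean log2 value differed by 0.44 (5.20 ± 0.31 against 4.75 ± 0.27), with a two-sided exact p of 0.114, and by 0.39 with an exact p of 0.2 without KRasG12D 4. The test does not decide here either.

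Clonal differences between mice may place the antibody segments among the leading genes, since each mouse carries its own expanded plasma cell clones. This would apply only if the libraries came from separate mice, which the labels do not say. Xist and Ddx3y show only that the libraries of a genotype did not all come from the same mouse. The median spread of variable segments within a genotype was 6.07 times that of other genes matched on mean level (SDs of 1.44 and 0.238 on the log2 scale), but a wide spread within groups does not by itself place a gene among the smallest p, so this decides nothing. Of the 35 splits of the 8 libraries, 3, the real one included, placed at least 11 segments among the 50 genes with the smallest p (highest other 15, median of the others 4), and 3 placed at least 10 there in one direction (highest other 13). So differences between libraries without regard to genotype can place as many there. The source of such differences was not tested, be it clones, reads shared between segments or something else. A genotype difference is not excluded.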
